A study of Homo sapiens with 6 samples.

How the data were processed

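Poly(A) mRNA from U2OS cells was sequenced as non-directional libraries, per the labels, in 3 control and 3 MED13 IDR samples. The authors aligned reads with HISAT2 2.0.5 to GRCh38 and counted them per gene with featureCounts 1.5.0-p3, per the submitters' processing notes. The annotation release was not stated, and all 58735 genes carry the coordinates of GENCODE 29. The deposited table of counts holds raw reads per gene, whole numbers whose totals differ between samples. Per the file headers, the same table gives gene length in bases, which is the other unit used. The deposited FPKM table divides each count by gene length and by a scaled library total, 0.974 to 1.05 times the sample's total count, and the authors' group columns equal the mean FPKM of the 3 samples. Of the samples' columns 0 were left unused.

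Genes were tested on the raw counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16511 of the 37423 genes with any count and at least 99.58% of the reads of a library. Libraries were scaled by TMM, with factors of 0.973 to 1.03. The quasi-likelihood test (glmQLFit, glmQLFTest) compared MED13 IDR with control, without covariates, and all gene p values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene counted as changed at an adjusted p under 0.05, in either direction, and as changed at least 2-fold when its log2 fold change also reached 1 in size. Fold changes are MED13 IDR over control, and CPM are counts-per-million of the TMM-scaled total. The biological coefficient of variation was 15.9%. The p values measure only the spread between these samples, since the labels do not say whether the replicates were separate cultures or transductions. Protein-coding genes took 96.1% to 96.4% of a library's reads and the 10 most abundant genes 6.28% to 6.82%. The first 2 principal components held 56.6% and 17.0% of the variance.

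For TNFSF8, with 0 counts in a group, a lower bound of the fold was computed against 3 counts over the group, and for CCL3 and DPYS, with 1 to 3 counts, an exact (Clopper-Pearson) 95% interval of the ratio. Intervals and floors cover counting error only.

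Lists of genes, 30 in all, together with the tests, thresholds and alternatives, were fixed before the data were examined. Symbols were matched for 99.8% of the list entries. The 29 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on edgeR's fit, with a preset correlation between genes of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run as alternatives.

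Genes were named by a rule. It took MED13 and the kinase module, and the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean of at least 1 CPM and groups that did not overlap. From each list past its threshold it took up to 4 members with the smallest p in the list's direction, and from each other list up to 2. This gave 97 genes, of which 92 passed the threshold. Genes named outside the rule are described as chosen after their values were seen.

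The numbers of the samples were checked for pairing. With group means removed, the correlations of control and MED13 IDR samples with the same number were 0.33, 0.25 and 0.40, above the limit of 0.1 set for pairing, and those of other numbers lay between -0.28 and -0.04. By this limit the numbers were taken to pair the samples. Removing group means pushes the other correlations below 0 when those of the same number lie above it, so they are no separate evidence. With 3 samples per group, a match of numbers by chance cannot be excluded. The fit with a replicate block is given beside a result where it changes the call or moves a count by more than 1.5 times. The main p values, SEs and leave-outs came from the fit without the block. Differences between replicate numbers therefore add to their spread, and a call lost there can still be firm with the block. No sequencing date or batch was given.

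Exon bases that overlap other genes, and transcript sequence shared with another gene at 98% identity or more over at least 100 bases, were computed from GENCODE 29 with blastn 2.17.0 for each named gene, because non-directional reads in overlapping exons cannot be assigned.

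The procedure was tested on simulated counts with 200 of 16511 genes changed. It recovered 13 of 67 genes changed 1.5-fold (19.4%), 42 of 67 changed 2-fold (62.7%) and 60 of 66 changed 4-fold (90.9%), and it called 10 unchanged genes (7.94% of calls). The shifted list was found (camera adjusted p = 4.89e-13) and 0 other lists were called. The simulated genes varied independently of each other, whereas the real mitosis list, for example, had an estimated correlation of 0.70. The simulation therefore cannot show how the list test behaves on lists whose genes correlate.

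The alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, no filter beyond a count above 0, a mean of at least 1 CPM, protein-coding genes only, the replicate block, a loess correction for gene length (with and without the block), an adjusted p under 0.01, limma-trend on log2(FPKM + 1), and leaving out each sample in turn. Figures were drawn with matplotlib 3.10.9.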

Results

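Messenger RNA was sequenced from U2OS cells, a human osteosarcoma line, in which the intrinsically disordered region (IDR) of MED13 was over-expressed from a lentivirus, and from control cells. MED13 belongs to the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II. There were 3 libraries per group. The labels do not say whether the control cells carried an empty vector or nothing. The comparison asks how cells that carry extra MED13 IDR differ in gene expression, as part of work on what this region does when transcription starts. The control libraries held 13404471, 9644426 and 10748693 counted reads, and the MED13 IDR libraries 9290455, 9495850 and 12984274. Between 26715 and 29624 genes had at least 1 count in a library. Of 58735 annotated genes, 16511 had enough counts to be tested.

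MED13 itself was 1.56-fold higher in the MED13 IDR cells. This gene (ENSG00000108510, GRCh38 chromosome 17, 61942605 to 62065282) rose from 407 ± 37.2 to 635 ± 77.6 counts-per-million (CPM; mean ± SD, n = 3 per group throughout). The log2 fold change was 0.64 (SE 0.12), with an edgeR adjusted p of 0.0074. The control libraries held 399.8, 447 and 374 CPM and the MED13 IDR libraries 677, 546 and 683 CPM, so every MED13 IDR library lay above every control library. Counts were deposited per gene, so reads from the over-expressed region and from the endogenous transcript were not separated. Reads from a construct with changed codons may not have been counted, and the labels do not give its codon use.

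**Figure D1:**
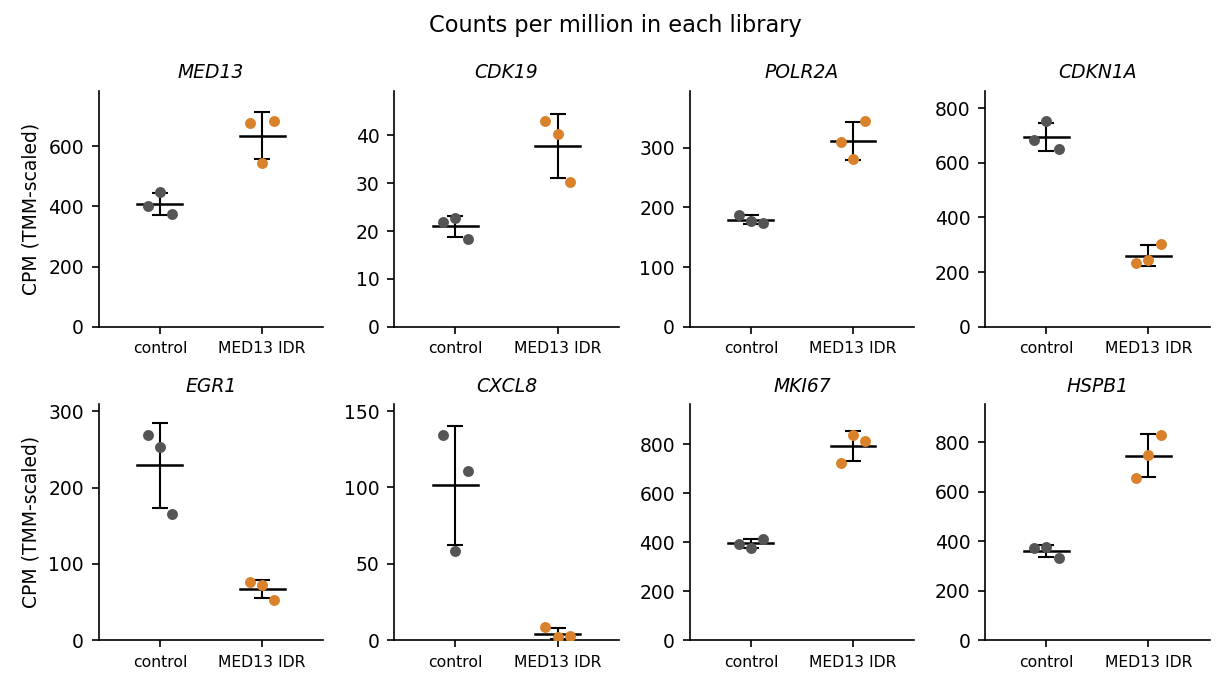
Expression in CPM (linear axis) of 8 genes in each of the 3 control and 3 MED13 IDR libraries. Points are libraries, horizontal lines are group means and error bars are the SD. MED13 lay at 374 to 447 CPM in control and at 546 to 683 CPM in MED13 IDR libraries.

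Expression differed in 3036 genes (18.4% of those tested), of which 1380 were higher and 1656 lower in MED13 IDR cells, although with upper-quartile scaling 1664 were higher and 1394 lower. Changes of at least 2-fold were found in 1016 genes, 427 higher and 589 lower (574 without MED13 IDR replicate 2, 207 higher and 367 lower). The falls reached further than the rises, since 39 genes were at least 8-fold lower and 4 at least 8-fold higher. Among 13497 protein-coding genes, 1218 were higher and 1452 lower, and among 781 long intergenic noncoding RNAs 50 were higher and 78 lower. Groups did not overlap in 2986 of the 3036 genes, and in 38.0% of all tested genes, where chance gives 10% for 3 against 3. A fit with the replicate number as a block found 5846 genes, 2777 higher and 3069 lower, including all 3036 in the same direction. Without MED13 IDR replicate 2 the count was 1234, without control replicate 1 it was 1863 and without control replicate 3 it was 1922.

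The 10 steepest falls included ESM1, CXCL8, IL1A and TNFSF8. ESM1, a secreted proteoglycan of vessel walls also called endocan, fell from 90.6 ± 49.0 to 2.42 ± 1.42 CPM, 38.1-fold (log2 -5.25, SE 0.45, edgeR adjusted p = 0.000419). The chemokine CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716) fell from 101 ± 38.8 to 4.35 ± 3.73 CPM, 23.9-fold (log2 -4.58, SE 0.47, adjusted p = 0.000534). IL1A, which encodes the cytokine interleukin-1 alpha, fell from 20.7 ± 10.1 to 0.994 ± 0.313 CPM, 20.4-fold (log2 -4.35, SE 0.41, adjusted p = 0.000459). TNFSF8, the ligand of the receptor CD30, had 179 counts over the control libraries and 0 over the MED13 IDR libraries, at least 55.9-fold lower against a floor of 3 counts over the group (adjusted p = 0.00578; exact lower 95% limit 44.99-fold). Of these counts 113 lay in control replicate 3, and without it the bound was 29.8-fold. The chemokine gene CCL3 had 80 against 1 counts, a ratio of 74.9 (exact 95% interval 13.1 to 2997, adjusted p = 0.00108), although 74.6% of its exon bases overlap a gene on the other strand and the libraries kept no strand. DPYS, an enzyme of pyrimidine breakdown, had 71 against 3 counts, a ratio of 22.2 (exact 95% interval 7.28 to 110, adjusted p = 0.00183). DCDC2C, a doublecortin-domain gene, fell by 4.64 on the log2 scale (SE 0.62, adjusted p = 0.00148), and INSC, an adaptor of spindle orientation, fell by 4.62 (SE 0.42, adjusted p = 0.000419). GPR65, a proton-sensing receptor, fell by 4.62 (SE 0.85, adjusted p = 0.00595), and NEURL3, a ubiquitin ligase, fell by 4.37 (SE 0.67, adjusted p = 0.00258). Leaving out 1 library moved some of these folds by over 1.5 times. The log2 change of CXCL8 was -5.49 without MED13 IDR replicate 1, that of GPR65 -3.77 without control replicate 3 and that of NEURL3 -3.48 without control replicate 1. Without MED13 IDR replicate 3, which held the 1 count of CCL3, the log2 changes of DCDC2C, GPR65 and NEURL3 were -5.69, -5.28 and -5.15.

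The 10 largest rises included BMF, LAMA4 and FREM2. BMF, a BH3-only activator of apoptosis (ENSG00000104081, chromosome 15, 40087890 to 40108892), rose 7.07-fold from 2.24 ± 0.818 to 15.8 ± 3.28 CPM (log2 2.82, SE 0.29, edgeR adjusted p = 0.000534). LAMA4, a laminin chain, rose from 5.41 ± 2.62 to 29.2 ± 15.9 CPM (log2 2.42, SE 0.45, adjusted p = 0.00644). FREM2, a basement-membrane protein, rose from 3.01 ± 2.13 to 16.4 ± 6.87 CPM (log2 2.45, SE 0.49, adjusted p = 0.00887). CNTNAP2, a neurexin-family adhesion protein, rose from 1.85 ± 0.33 to 10.6 ± 3.96 CPM (log2 2.51, SE 0.34, adjusted p = 0.0015). APOL4, an apolipoprotein L gene, rose from 0.263 to 2.84 CPM (log2 3.35, SE 0.53, adjusted p = 0.00299), and DOC2B, a calcium sensor of vesicle release, rose by log2 2.86 (SE 0.56, adjusted p = 0.00776). SMIM11A rose from 0.453 to 4.20 CPM (log2 3.19, SE 0.44, adjusted p = 0.00171), but 100% of its transcript is shared with SMIM11B, so its reads cannot be placed with certainty. The receptor subunit GABRR1 (log2 3.08, SE 0.85, adjusted p = 0.0313) rose with a MED13 IDR SD of 2.71 on a mean of 2.84 CPM, and lost its call in 4 leave-outs (log2 1.96, adjusted p = 0.111 without MED13 IDR replicate 1, and log2 4.11 without control replicate 1). MYOCD, a coactivator of smooth-muscle genes (log2 2.44, SE 0.54, adjusted p = 0.0135), and RARRES2, which encodes the adipokine chemerin (log2 2.37, SE 0.55, adjusted p = 0.0151), rose too. Without MED13 IDR replicate 2 their adjusted p values were 0.0598 and 0.0591, and without control replicate 2 the log2 change of MYOCD was 3.12.

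**Figure D2:**
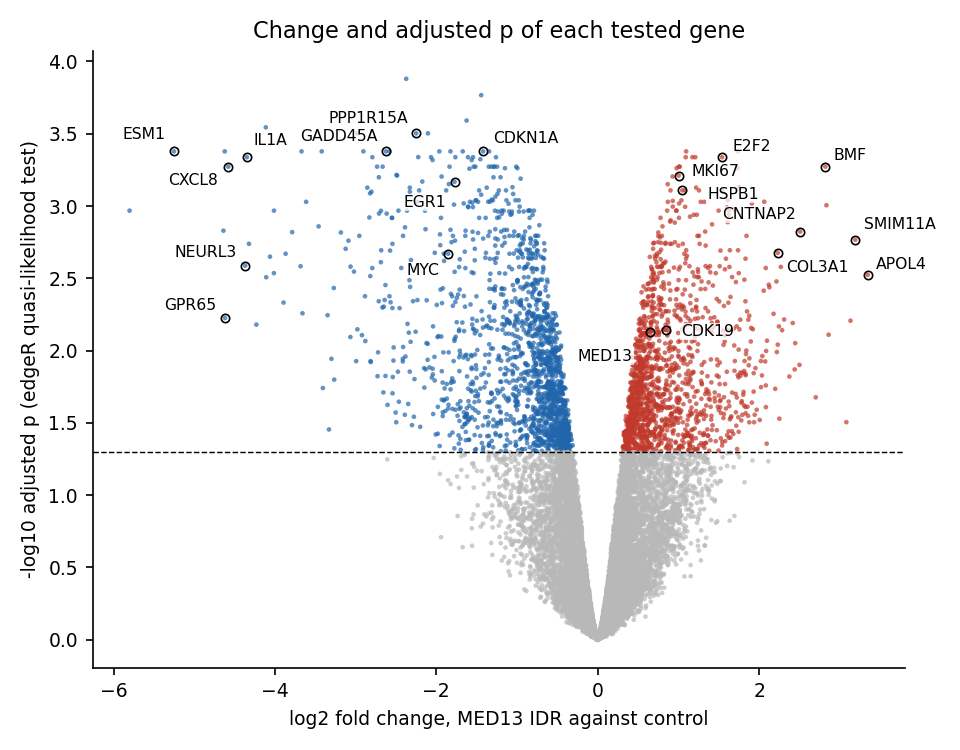
Log2 fold change, MED13 IDR over control (x axis), against -log10 of the edgeR adjusted p (y axis), for the 16509 tested genes with counts in both groups. The dashed line marks the adjusted p threshold of 0.05. The 1656 genes that fell reach further from 0 than the 1380 that rose.

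In the kinase module, 2 of 7 genes rose, MED13 and CDK19, while 5 did not pass the threshold. CDK19 (ENSG00000155111, chromosome 6, 110609978 to 110815958), a kinase of the module, rose 1.8-fold from 20.97 ± 2.24 to 37.8 ± 6.74 CPM (log2 0.85, SE 0.16, edgeR adjusted p = 0.0072). Its paralog CDK8 had 39.3 ± 4.79 and 32.6 ± 0.713 CPM (log2 -0.27, SE 0.13, adjusted p = 0.166), and the cyclin partner CCNC, with 19.3% of its transcript shared with another gene, had a log2 change of 0.07 (SE 0.14, adjusted p = 0.763). MED12, which activates the kinases, had a log2 change of -0.23 (SE 0.14, adjusted p = 0.256), and with the replicate block it fell (log2 -0.23, adjusted p = 0.0358). Its paralog MED12L, which shares 33.3% of its transcript with IGSF10 (log2 -0.18, SE 0.24, adjusted p = 0.646), and MED13L (log2 -0.20, SE 0.11, adjusted p = 0.228) did not pass. The module's median log2 change was -0.18, its mean 0.10 and its camera test pointed up (adjusted p = 0.671). CCNC turned below 0 without control replicate 1 and MED12L above 0 without control replicate 2 or MED13 IDR replicate 1.

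Among 26 core Mediator subunits 2 rose, 2 fell and 22 did not pass (median log2 0.03, camera adjusted p = 0.76). MED10, of the middle module, fell from 70.5 ± 10.1 to 45.6 ± 5.11 CPM (log2 -0.63, SE 0.14, edgeR adjusted p = 0.0126; 0.0629 without MED13 IDR replicate 2). MED28 had a log2 change of 0.41 (SE 0.12, adjusted p = 0.0326), but shares 32.4% of its transcript with FAM184B and its call was lost in each of the 6 leave-outs. Named after their values were seen, MED7 was higher (log2 0.54, adjusted p = 0.0348) and MED15 lower (log2 -0.34, adjusted p = 0.0377), but MED7 lost its call in 4 leave-outs and MED15 in all 6. Of 12 RNA polymerase II subunits 1 passed, POLR2A, which encodes the catalytic subunit and rose from 179 ± 7.04 to 311 ± 31.8 CPM (log2 0.80, SE 0.11, adjusted p = 0.00161); with the block 4 rose and 1 fell (median log2 0.16, camera adjusted p = 0.282). Of 30 general transcription factors 2 rose and 5 fell (median log2 -0.06, camera adjusted p = 0.594), against 3 and 8 with the block. GTF2H1, a subunit of TFIIH, fell (log2 -0.59, SE 0.12, adjusted p = 0.00805), as did TAF3, a TFIID subunit (log2 -0.56, SE 0.12, adjusted p = 0.00984). Chosen after their values were seen, the TFIIH kinase CDK7 (log2 -0.60, adjusted p = 0.0147), its cyclin CCNH, with 22.3% of its exon bases overlapping other genes (log2 -0.61, adjusted p = 0.0166), and TAF13 (log2 -0.74, adjusted p = 0.019) also fell, each with no call in 2 leave-outs. Likewise chosen, GTF2A1 rose (log2 0.53, adjusted p = 0.0174; no call in 2 leave-outs), and TAF6 had a log2 change of 0.37 (adjusted p = 0.0415) with 33.8% of its transcript shared with AP4M1 and no call in 5 leave-outs.

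The lists of immediate-early genes, p53 targets and ATF4 and unfolded protein response genes were lower with camera's preset correlation. Of 26 immediate-early genes, which respond within minutes to growth factors, 18 fell (22 adjusted over the list alone) and 0 rose, with a median log2 change of -0.84 (camera adjusted p = 4.85e-16, adjusted p = 0.0565 with an estimated correlation). EGR1, a zinc-finger factor, fell from 229 ± 55.7 to 67.2 ± 12.2 CPM (log2 -1.77, SE 0.19, edgeR adjusted p = 0.00068). CTGF, a matricellular protein, fell from 476 ± 53.6 to 156 ± 32.3 CPM (log2 -1.61, SE 0.15, adjusted p = 0.000459). The AP-1 subunits FOSL1 (log2 -1.61, SE 0.20, adjusted p = 0.00101) and JUN (log2 -0.77, SE 0.11, adjusted p = 0.00161) fell as well. Of 26 p53 targets 19 fell and 0 rose (median log2 -0.74, camera adjusted p = 1.66e-19, adjusted p = 0.165 with an estimated correlation). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), the p21 inhibitor of cyclin-dependent kinases, fell 2.68-fold from 696 ± 51.4 to 260.0 ± 38.6 CPM (log2 -1.42, SE 0.13, adjusted p = 0.000419). MDM2, the ubiquitin ligase of p53, fell from 294 ± 23.2 to 146 ± 3.64 CPM (log2 -1.01, SE 0.10, adjusted p = 0.000534). So did the death receptor FAS (log2 -1.32, SE 0.13, adjusted p = 0.000534) and the stress sensor SESN2 (log2 -1.29, SE 0.13, adjusted p = 0.000534). In the list of ATF4 and unfolded protein response genes, 13 of 25 fell and 0 rose (15 and 3 adjusted over the list alone; with the block 15 and 4). Its median log2 change was -0.43 (camera adjusted p = 3.55e-07, adjusted p = 0.0565 with an estimated correlation). PPP1R15A, a phosphatase subunit that ends the integrated stress response, fell from 128 ± 20.8 to 26.8 ± 5.69 CPM (log2 -2.25, SE 0.18, adjusted p = 0.000314). ATF3 fell from 80.4 ± 8.91 to 19.6 ± 10.6 CPM (log2 -2.02, SE 0.29, adjusted p = 0.00211), and DDIT3, with 39.6% of its exon bases overlapping other genes, changed by log2 -2.07 (SE 0.20, adjusted p = 0.000459).

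The lists of NF-kB targets and interferon-stimulated genes were lower as well with camera's preset correlation. Of 19 NF-kB and inflammatory targets 12 fell (14 adjusted over the list alone) and 0 rose, with a median log2 change of -1.70 (camera adjusted p = 4.17e-11, adjusted p = 0.276 with an estimated correlation). Beside CXCL8 and IL1A, the growth factor CSF2 fell from 7.64 ± 1.93 to 1.39 ± 0.258 CPM (log2 -2.47, SE 0.31, edgeR adjusted p = 0.00108), and the NF-kB subunit NFKB2 from 228 ± 23.8 to 109 ± 17.1 CPM (log2 -1.07, SE 0.14, adjusted p = 0.00114). Of 29 interferon-stimulated genes 15 fell (17 adjusted over the list alone) and 0 rose (median log2 -0.82, camera adjusted p = 4.79e-07, adjusted p = 0.376 with an estimated correlation). The exonuclease ISG20 (log2 -1.47, SE 0.17, adjusted p = 0.000779), the RNA sensor DDX58 (log2 -1.03, SE 0.14, adjusted p = 0.0015), the antiviral IFIT3 (log2 -1.99, SE 0.35, adjusted p = 0.00483) and OASL (log2 -1.03, SE 0.20, adjusted p = 0.0068) fell. Blood cell markers were measured beside these groups. Of 6 tested, 2 were lower, the T-cell gene CD3D, from 2.39 to 0.579 CPM (log2 -1.98, SE 0.57, adjusted p = 0.0376), and the myeloid integrin ITGAM, from 6.36 to 1.82 CPM (log2 -1.83, SE 0.53, adjusted p = 0.0385). Their list had a median of -0.89 and did not pass (camera adjusted p = 0.147; adjusted p = 0.48 with an estimated correlation), but it passed without control replicate 2 (median -1.14, camera adjusted p = 0.0438). CD3D lost its call in 4 leave-outs and ITGAM in 3 (highest adjusted p = 0.147 at log2 -1.21 without control replicate 3, and 0.158 without control replicate 1). Without MED13 IDR replicate 1 the log2 change of ITGAM was -2.59.

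Targets of YAP and TAZ, which respond to cell shape and contact, were lower as a group, with 6 of 21 falling and 0 rising (11 and 2 adjusted over the list alone; with the block 13 and 4). The median log2 change was -0.32 (camera adjusted p = 7.54e-06, adjusted p = 0.253 with an estimated correlation). GADD45A, a growth-arrest gene, fell from 378 ± 78.2 to 61.0 ± 20.0 CPM (log2 -2.62, SE 0.23, edgeR adjusted p = 0.000419), and ANKRD1, a muscle and stress protein, from 349 ± 71.6 to 103 ± 16.7 CPM (log2 -1.76, SE 0.17, adjusted p = 0.000459). DLC1 fell from 111 ± 12.5 to 62.3 ± 3.91 CPM (log2 -0.83, SE 0.12, adjusted p = 0.00167). CTGF, counted above among immediate-early genes, belongs to this list too. Other lists share members as well, so they are not independent of each other. Among others, the immediate-early list also holds ATF3 (ATF4 list), MYC (Wnt list) and KLF10 (TGF-beta list). SESN2 is in the p53 and ATF4 lists, and SLC7A11 in the ATF4 and NRF2 lists.

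The lists of mitosis and replication genes were higher. Of 30 mitosis genes 21 rose (27 adjusted over the list alone) and 0 fell, with a median log2 change of 0.61 (camera adjusted p = 1.36e-16, adjusted p = 0.376 with an estimated correlation). MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385), which coats mitotic chromosomes, rose 2.0-fold from 395 ± 16.9 to 791 ± 60.9 CPM (log2 1.0, SE 0.11, edgeR adjusted p = 0.000615). The kinesin KIF20A rose from 77.7 ± 11.9 to 165 ± 16.2 CPM (log2 1.08, SE 0.13, adjusted p = 0.00101), the kinetochore gene CENPF from 280 ± 10.3 to 562 ± 90.6 CPM (log2 1.01, SE 0.13, adjusted p = 0.00121) and the topoisomerase TOP2A from 572 ± 19.5 to 917 ± 74.5 CPM (log2 0.68, SE 0.11, adjusted p = 0.00294). Of 30 replication genes 15 rose (18 adjusted over the list alone) and 0 fell (median log2 0.38, camera adjusted p = 7.97e-10, adjusted p = 0.153 with an estimated correlation). E2F2, a transcription factor of the G1 to S step, rose from 12.9 ± 1.30 to 37.6 ± 3.89 CPM (log2 1.54, SE 0.15, adjusted p = 0.000459). The replicative helicase subunits MCM6 (log2 0.84, SE 0.12, adjusted p = 0.00183) and MCM3 (log2 0.65, SE 0.10, adjusted p = 0.00225) rose, and MCM2 (log2 0.70, SE 0.10, adjusted p = 0.0018) had 30.8% of its transcript shared with another gene. Histone genes, whose poly(A)-free mRNAs are captured poorly, did not move together, with 2 of 10 higher and 1 lower (median log2 0.09, mean -0.02, camera adjusted p = 0.753, direction up). HIST1H1E, a linker histone, fell (log2 -2.41, SE 0.49, adjusted p = 0.00944), and HIST1H1C, chosen after its value was seen, rose (log2 0.65, adjusted p = 0.0304; no call in 4 leave-outs). HIST1H2BK (log2 1.08, SE 0.27, adjusted p = 0.02) shares 100% of its sequence with H2BFS and lost its call without control replicate 1 (adjusted p = 0.0781).

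Both lists of lipid synthesis genes were higher with camera's preset correlation. Of 24 cholesterol synthesis genes 13 rose and 0 fell (15 and 0 adjusted over the list alone, 17 and 1 with the block), with a median log2 change of 0.47 (camera adjusted p = 2.47e-06, adjusted p = 0.48 with an estimated correlation). The isomerase EBP rose from 37.6 ± 4.49 to 63.5 ± 10.5 CPM (log2 0.76, SE 0.15, edgeR adjusted p = 0.00782) and the decarboxylase MVD from 46.4 ± 3.08 to 72.5 ± 10.9 CPM (log2 0.64, SE 0.13, adjusted p = 0.00934). The sterol carrier STARD4 (log2 0.54, SE 0.11, adjusted p = 0.00892; 0.051 without MED13 IDR replicate 2) and the isomerase IDI1, 14.8% of whose exon bases overlap other genes (log2 0.73, SE 0.14, adjusted p = 0.0064), were also higher. Of 12 fatty acid synthesis genes 4 rose (7 adjusted over the list alone, 7 with the block) and 0 fell (median log2 0.31, camera adjusted p = 0.00326, adjusted p = 0.441 with an estimated correlation). The desaturase FADS2 rose from 247 ± 25.7 to 428 ± 66.8 CPM (log2 0.79, SE 0.13, adjusted p = 0.00435), and SREBF1, the transcription factor of this pathway, from 114 ± 5.07 to 197 ± 34.6 CPM (log2 0.78, SE 0.13, adjusted p = 0.00442). The ligase ACSL3 rose by log2 0.49 (SE 0.10, adjusted p = 0.0086), and the desaturase SCD by log2 0.57 (SE 0.17, adjusted p = 0.044), with overlapping groups and no call in 5 leave-outs (highest adjusted p = 0.164 without MED13 IDR replicate 2).

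Of 14 heat shock genes 4 rose (7 with the block) and 0 fell, with a median log2 change of 0.17 (camera adjusted p = 0.0132, adjusted p = 0.48 with an estimated correlation). HSPB1, a small chaperone, rose from 361 ± 24.1 to 747 ± 86.6 CPM (log2 1.05, SE 0.12, edgeR adjusted p = 0.000779). The chaperones HSPA1A and HSPA1B, which share 86.7% and 85.3% of their transcripts with each other, and CRYAB, with 22.5% of its transcript shared with HSPB2, each had a log2 change of 0.49 (adjusted p = 0.0161, 0.0321 and 0.0266). The list lost its call without control replicate 2 (adjusted p = 0.0507) and without MED13 IDR replicate 3 (adjusted p = 0.0896). HSPA1A lost its call without control replicate 3 (adjusted p = 0.0524), as did CRYAB and HSPA1B (adjusted p = 0.0813 and 0.0936), which had no call in 3 and 5 leave-outs.

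**Figure D3:**
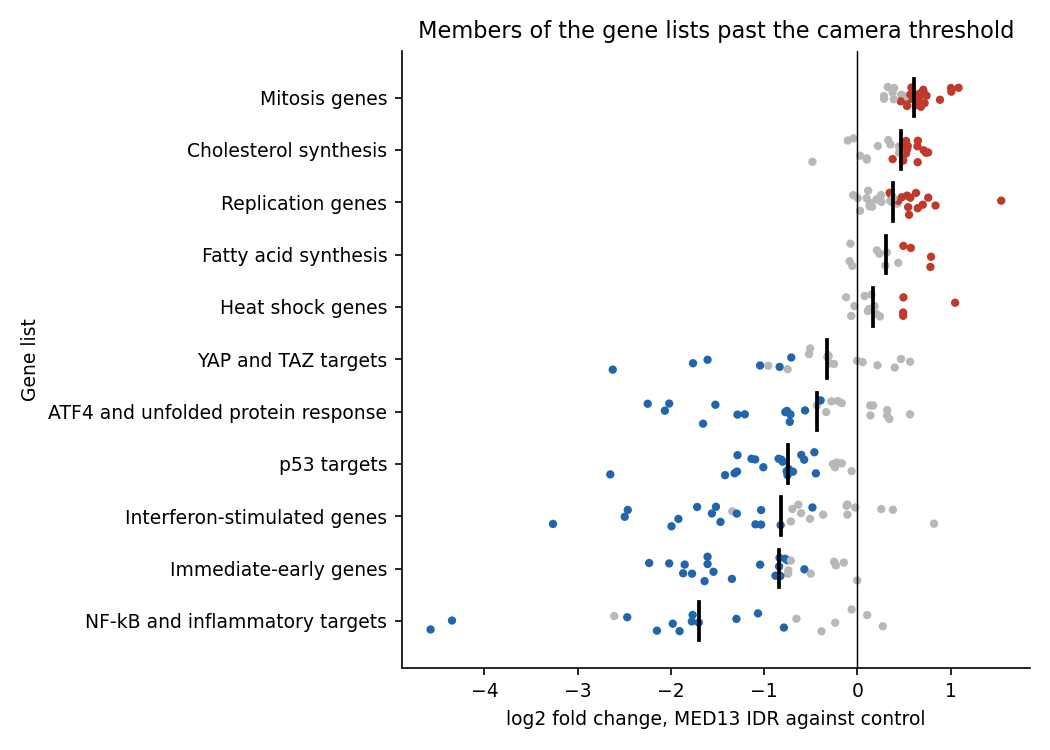
Log2 fold change, MED13 IDR over control (x axis), of the tested members of the 11 gene lists past the threshold, with a point per gene and a bar at each list's median. Of these lists 5 were higher and 6 lower.

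In all, 11 of 29 tested lists passed camera with its preset correlation of 0.01, and with an estimated correlation none did (0 lists, smallest adjusted p = 0.0565; 5 lists at an unadjusted p under 0.05). The directional fry test, which asks whether a list's genes move on balance one way, passed 7, and within the fit with the replicate block it passed 0 (smallest adjusted p = 0.0769). Of the 11 lists, those of interferon-stimulated, fatty acid synthesis, cholesterol synthesis and heat shock genes did not pass fry without the block (adjusted p = 0.0682, 0.0682, 0.071 and 0.071). Counts adjusted over the list alone equalled those over all genes in 16 of the 30 lists.

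Other signalling targets moved in both directions. Of 22 hypoxia targets 2 rose and 3 fell (with the block 3 and 8; median log2 -0.09, camera adjusted p = 0.393). The glycolytic kinase HK2 fell from 129 ± 26.9 to 42.4 ± 10.4 CPM (log2 -1.60, SE 0.20, edgeR adjusted p = 0.00102), and the angiogenic factor VEGFA from 105 ± 14.1 to 59.9 ± 15.8 CPM (log2 -0.80, SE 0.18, adjusted p = 0.0151; 0.0555 without control replicate 2). Chosen after their values were seen, NDRG1 was lower (log2 -0.41, adjusted p = 0.0324; no call in 5 leave-outs) and BNIP3L (log2 0.43, adjusted p = 0.0204; no call in 3 leave-outs) and EGLN3 (log2 1.24, adjusted p = 0.019; no call in 2) rose. Of 12 Wnt targets 2 rose and 1 fell (4 and 2 adjusted over the list alone and with the block; median log2 0.12, camera adjusted p = 0.855). The growth regulator MYC fell from 269 ± 39.6 to 74.3 ± 33.4 CPM (log2 -1.85, SE 0.27, adjusted p = 0.00214), and the feedback inhibitors AXIN2, 25.2% of whose exon bases overlap other genes (log2 1.0, SE 0.21, adjusted p = 0.0108), and NKD1, chosen after its value was seen (log2 0.87, adjusted p = 0.0413; no call in 4 leave-outs), rose. Of 19 TGF-beta targets 1 rose and 2 fell (3 and 3 with the block; median log2 -0.01, mean 0.03, camera adjusted p = 0.895, direction down). SMAD6, an inhibitory SMAD, rose from 8.38 ± 3.85 to 27.0 ± 0.757 CPM (log2 1.67, SE 0.26, adjusted p = 0.0031). KLF10, chosen after its value was seen, fell (log2 -0.83, adjusted p = 0.00915; no call without MED13 IDR replicate 2). Of 7 Notch targets 1 rose and 2 fell (2 and 2 with the block; median log2 -0.03, camera adjusted p = 0.594). The ligand JAG1 fell (log2 -1.24, SE 0.18, adjusted p = 0.00211), DTX4 fell (log2 -0.66, SE 0.16, adjusted p = 0.0204; 0.0718 without control replicate 3) and the receptor NOTCH3, chosen after its value was seen, rose (log2 0.52, adjusted p = 0.0345; no call in 3 leave-outs).

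Of 19 NRF2 targets 4 fell and 0 rose (median log2 -0.21, camera adjusted p = 0.076). With the replicate block 7 fell and the list passed camera (adjusted p = 0.0151) but not fry (adjusted p = 0.0847). Without the block it had an adjusted p = 0.441 with an estimated correlation. It also passed camera without a low-count filter (adjusted p = 0.00352), without control replicate 2 (adjusted p = 0.0185) and without MED13 IDR replicate 1 (adjusted p = 0.0234). HMOX1, which degrades heme, fell (log2 -1.04, SE 0.21, adjusted p = 0.00892), as did OSGIN1, with 13.9% of its exon bases overlapping other genes (log2 -1.64, SE 0.25, adjusted p = 0.00269), and, chosen after their values were seen, TXNRD1 (log2 -0.88, adjusted p = 0.0126) and SLC7A11 (log2 -0.72, adjusted p = 0.0454; no call in 4 leave-outs).

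Matrix and bone genes showed a few large changes. Of 27 extracellular matrix genes 3 rose and 0 fell (10 and 8 with the block; median log2 0.14, camera adjusted p = 0.393). COL3A1, a fibrillar collagen, rose from 17.2 ± 7.43 to 80.7 ± 29.5 CPM (log2 2.23, SE 0.33, edgeR adjusted p = 0.00211), next to LAMA4 and, chosen after its value was seen, SPARC (log2 0.59, adjusted p = 0.0143; no call without MED13 IDR replicate 2). Without MED13 IDR replicate 3 the list passed (camera adjusted p = 0.00631). With all libraries it had an adjusted p = 0.925 with an estimated correlation. Of 11 osteoblast genes 2 rose and 2 fell (4 and 4 adjusted over the list alone, 4 and 5 with the block; median log2 -0.34, camera adjusted p = 0.759). Over 16 alternative settings this list's median ran from -0.35 to 0.15, and camera pointed down in 12 of them. RUNX2, a regulator of bone formation, rose from 20.6 ± 6.11 to 44.1 ± 3.16 CPM (log2 1.09, SE 0.20, adjusted p = 0.00575), while ALPL, a phosphatase of mineralisation, fell from 19.0 ± 0.193 to 6.45 ± 1.25 CPM (log2 -1.55, SE 0.19, adjusted p = 0.000948). Chosen after their values were seen, BMP2 fell (log2 -1.02, adjusted p = 0.00791) and BMP4 rose (log2 1.39, adjusted p = 0.0218; no call in 3 leave-outs).

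Of 36 ribosomal protein genes 1 rose, RPL22, with 16.5% of its transcript shared with other genes (log2 0.54, SE 0.12, edgeR adjusted p = 0.0142; 0.0537 without control replicate 2), and with the block 2 rose and 2 fell (median log2 0.03, camera adjusted p = 0.759). Of 13 mitochondrially encoded mRNAs 0 rose and 1 fell (0 and 0 adjusted over the list alone, 3 and 2 with the block; median log2 0.02, camera adjusted p = 0.855). That gene was MT-ATP8 (log2 -0.39, SE 0.11, adjusted p = 0.0392), which overlaps other genes in 22.2% of its bases and lost its call in 5 leave-outs (highest adjusted p = 0.162 without MED13 IDR replicate 2). Mitochondrial genes took 5.99% to 6.42% of the reads of a library.

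With all libraries, no tested list of markers of another cell type passed, and blood cell markers, given above, passed without control replicate 2. Of 8 epithelial markers 1 was higher (2 higher and 1 lower adjusted over the list alone, 2 and 2 with the block; median log2 0.20, camera adjusted p = 0.753). Their median was -0.11 without a low-count filter and 0.008 without MED13 IDR replicate 2. The keratin gene KRT14 had a log2 change of 1.31 (SE 0.38, edgeR adjusted p = 0.0384), with overlapping groups and no call in 4 leave-outs (highest adjusted p = 0.12 without MED13 IDR replicate 2). Of 7 endothelial markers 2 were lower (median log2 -0.12, camera adjusted p = 0.594), the receptor kinase TIE1 (log2 -2.73, SE 0.63, adjusted p = 0.015; 0.0528 without control replicate 1) and the adhesion protein PECAM1 (log2 -1.21, SE 0.35, adjusted p = 0.0386; 0.13 without control replicate 3). Of 10 neural markers 2 were higher and 2 lower (median log2 0.06, mean 0.13, camera adjusted p = 0.863, direction down). The synaptic vesicle gene SYP fell from 45.8 ± 8.66 to 9.17 ± 3.93 CPM (log2 -2.33, SE 0.27, adjusted p = 0.000796), and OLIG2 fell from 14.2 ± 0.83 to 6.98 ± 2.48 CPM (log2 -1.01, SE 0.24, adjusted p = 0.0186; 0.0759 without MED13 IDR replicate 2). Chosen after their values were seen, MAP2 (log2 1.72, adjusted p = 0.0211; no call in 4 leave-outs) and SOX2 (log2 2.25, adjusted p = 0.0296; no call in 3) were higher, SOX2 with 38.7 ± 27.5 CPM in MED13 IDR cells. With the block the edgeR adjusted p was 3.17e-05 for MAP2 and 1.03e-07 for SOX2. The adipocyte and muscle list had 3 tested genes, too few for a list test. TNNT1, a troponin of slow muscle, rose from 115 ± 8.73 to 193 ± 7.16 CPM (log2 0.75, SE 0.10, adjusted p = 0.00152; 2 genes were higher adjusted over the list alone, and with the block 2 were higher and 1 lower).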

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

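The fry test within the blocked fit was not among the alternatives fixed in advance and was chosen after seeing the data. The count of 3036 changed genes stayed within 1.5 times under RLE (3043), upper-quartile (3058) and library-size scaling (2990), DESeq2 (3227), limma-voom (2951), no filter (3976), a mean of at least 1 CPM (3011), protein-coding genes alone (2716), the length correction (3072) and limma-trend on FPKM (2520). It was 5846 with the replicate block, 5933 with the block and length correction, and 1026 at an adjusted p under 0.01. Leaving out a library gave 1234 to 2998 genes (1234 without MED13 IDR replicate 2, 1863 without control replicate 1, 1922 without control replicate 3), and 574 to 1226 genes changed at least 2-fold (574 without MED13 IDR replicate 2). At 0.01 the stricter threshold lowers the count by construction, and for the other changes in these counts the cause was not tested. No gene of the 3036 was called in the opposite direction (0 under each alternative fitted to counts). Upper-quartile scaling made 54.4% of the changed genes higher, against 45.5%. MED13 stayed higher in each leave-out and in each alternative that gave it a value (limma-trend on FPKM was run for the count of genes alone), with a log2 change of 0.59 to 0.75 and an adjusted p of at most 0.0303. The median log2 change of all tested genes was -0.00041, and 0.0040 with RLE, 0.047 with upper-quartile scaling, 0.0046 with DESeq2, 0.0123 without a filter and -0.0078 to 0.0114 over the leave-outs; the cause was not tested. Of the lists, 11 passed, 0 with an estimated correlation, 7 with fry in its directional form, 27 in its mixed form and 11 to 12 in the leave-outs; within the blocked fit the directional fry test passed 0 (smallest adjusted p = 0.0769). DESeq2 gave no list test. CCNC ranged from -0.015 to 0.21 over the leave-outs (log2, below 0 without control replicate 1) and MED12L from -0.34 to 0.0755 (above 0 without control replicate 2 and without MED13 IDR replicate 1), neither past the threshold; the cause was not tested. Of the 97 genes named by the rule, 21 lost their call in at least 1 leave-out, 12 without control replicate 1 (adjusted p = 0.0502 to 0.158), 11 without control replicate 2 (0.0537 to 0.111), 12 without control replicate 3 (0.0523 to 0.147), 9 without MED13 IDR replicate 1 (0.0546 to 0.111), 14 without replicate 2 (0.051 to 0.164) and 4 without replicate 3 (0.0642 to 0.101). Of the 21 list members named after their values were seen, 19 lost theirs in at least 1 leave-out, all 19 without MED13 IDR replicate 2. SCD, KRT14, CD3D and PECAM1 lost their calls with limma-voom (adjusted p = 0.0501, 0.0503, 0.0697 and 0.068), MT-ATP8 with upper-quartile scaling (0.0548) and MED28 without a filter (0.063). Counts were simulated at this depth with 200 of 16511 genes changed. With 3 samples per group and no block, 19.4% of the simulated 1.5-fold changes were found. In the data 3036 genes were called, and the Benjamini-Hochberg cutoff depends on how many genes change. The simulated share therefore does not give the share of 1.5-fold changes found in the data.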

Other observations

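The gene families, LMNB1, MALAT1, PVT1 and the other genes named here outside the rule, the choice of patterns and CBSL, and the tests of a gain confined to the protocadherin cluster and of shared exons in PCDHA and PCDHG genes alone, were chosen only after the results were seen.

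All 3 tested HMGB genes, which bend DNA, were higher, with a median log2 change of 0.93 (0.93 to 0.98 over 3 other scalings), and so were 4 of 5 HMGN genes, which bind nucleosomes. HMGN2 rose from 276 ± 11.2 to 554 ± 31.3 CPM (log2 1.01, SE 0.10, edgeR adjusted p = 0.000534; n = 3 per group). LMNB1, a lamin of the nuclear envelope, rose from 192 ± 11.9 to 411 ± 12.9 CPM (log2 1.10, SE 0.10, adjusted p = 0.000419). Of 6 SMC genes, which encode chromosome-structure proteins such as those of cohesin and condensin, 4 were higher (3 without control replicate 1 or without MED13 IDR replicate 2), among them SMC2 (log2 0.78, adjusted p = 0.00121) and SMC1A (log2 0.66, adjusted p = 0.00643). HMGN calls numbered 3 without control replicate 1, control replicate 2 or MED13 IDR replicate 2.

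Of 19 tested genes named as small nucleolar RNA hosts, 6 fell and 0 rose (8 and 1 with the replicate block). Without control replicate 1 or without MED13 IDR replicate 2, 3 fell. Their median log2 change was -0.33 (-0.33 to -0.28 over 3 other scalings). Over the leave-outs it ran from -0.38 without MED13 IDR replicate 3 to -0.19 without control replicate 3. SNHG17 fell from 22.3 ± 1.76 to 12.3 ± 2.15 CPM (log2 -0.86, SE 0.17, edgeR adjusted p = 0.00884), and GAS5, another host gene, from 137 ± 11.7 to 87.4 ± 13.6 CPM (log2 -0.65, SE 0.13, adjusted p = 0.00856). The nuclear RNA MALAT1 fell from 397 ± 10.6 to 227 ± 17.4 CPM (log2 -0.81, SE 0.10, adjusted p = 0.00115), and PVT1, next to MYC on chromosome 8, from 76.6 ± 6.79 to 25.9 ± 5.17 CPM (log2 -1.56, SE 0.15, adjusted p = 0.000481).

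The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 3036 genes and the highest of the others 0 (96 to 1108 genes at an unadjusted p under 0.05, against 5603). Of the 4 splits that part all 3 pairs, the real split gave 3036 genes and the others 0 (116, 96 and 122 at an unadjusted p under 0.05). Each split other than the real one puts libraries of both groups on each side. The difference between the groups then adds to the spread and lowers the count, so these counts of 0 do not show what chance gives.

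The lists of immediate-early, p53, NF-kB and interferon genes were lower and that of mitosis genes higher in MED13 IDR cells with camera's preset correlation, and none of these 5 passed with an estimated correlation (adjusted p = 0.0565, 0.165, 0.276, 0.376 and 0.376). For blood cells in the control libraries, the median control level of 12 abundant leukocyte genes was 0.616 CPM, and 8 of them lay under 1 CPM. That median was below the limit used, the lowest CCL3 value of a control library (1.78 CPM). The genes straddled the limit, however, with LAPTM5 and SRGN at 7.86 and 8.10 CPM in control. Both fell, LAPTM5 by log2 -2.11 (edgeR adjusted p = 0.0116, no call in 1 leave-out) and SRGN by log2 -1.74 (adjusted p = 0.0282, no call in 3). CORO1A, the highest at 8.91 CPM, did not pass (log2 -0.18, adjusted p = 0.634), nor did RAC2 at 3.66 CPM (log2 -1.49, adjusted p = 0.118). CD52 and PTPRCAP had 0 counts in control. The median therefore does not settle whether blood cells were present. The choice among the scalings tried was argued against as the source, since the smallest median of these 5 lists was 0.611 in size over 3 other scalings. In these the median of all genes was at most 0.047 in size, so they differed too little to turn such a median. A change of all mRNAs together cannot be seen under any of them, since each scales the libraries to each other. A senescence-like state in part of the control cells is a hypothesis that stays open: 3 of 3 genes that fall in such cells, LMNB1, HMGB1 and HMGB2, were higher in MED13 IDR cells, but these may also be lower in any slowly cycling culture. The effect of the MED13 IDR, any effect of carrying a lentivirus, and any difference in density or handling between the cultures were not tested apart. What the control cells carried is not stated in the labels.

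SMIM11A rose and CBSL (log2 -3.33, SE 0.95, adjusted p = 0.0351) fell, and each has a near-identical copy. Counted reads moved between copies were argued against for SMIM11A, where the summed counts of SMIM11A and SMIM11B changed by log2 3.11, with 144 counts on SMIM11A and 2 on SMIM11B. Reads that matched both copies and were not counted cannot be seen in this sum. For CBSL, moved reads may account for the fall, since the sum with its copy CBS changed by log2 -0.30 (SE 0.39, adjusted p = 0.632). Control replicate 2 held 151 counts of CBSL, against 23 and 14 in the other controls, and 155 of CBS, against 337 and 230. CBSL lost its call in 4 leave-outs, without control replicate 2 among them.

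Clustered protocadherin genes on chromosome 5 (140786136 to 141512981), most of which encode neuronal adhesion proteins, were mostly above 0. Of 16 tested PCDHB genes 10 were higher (14 with the block, 6 without MED13 IDR replicate 2, 13 without MED13 IDR replicate 3). The 10 include PCDHB17P and PCDHB18P, which are named as pseudogenes (edgeR adjusted p = 0.0355 and 0.00805). All 16 lay above 0 (median log2 1.12). The 12 PCDHA genes held 1 that was higher (4 with the block, 2 without MED13 IDR replicate 3), with 10 above 0. The 14 PCDHG genes held 2 that were higher (6 with the block, 0 in 5 leave-outs). A copy-number gain reaching beyond the cluster was argued against: windows of 51 neighbouring genes reached a median of 0.861, beyond the 0.411 of 1000 random orders, and each of the 40 such windows overlapped the cluster, but 26 other genes in it or within 0.5 Mb had a median of 0.0076. A copy-number gain confined to the protocadherin cluster cannot be told apart from regulation, since only 2 of those 26 genes lie inside it, TAF7 (log2 0.16, SE 0.09, adjusted p = 0.234) and AC005618.1 (log2 1.83, SE 0.42, adjusted p = 0.0148, no call in 2 leave-outs). Reads in the exons that PCDHA or PCDHG genes share were argued against for the PCDHB genes (median 1.12), which lack those exons, but stay open for the PCDHA and PCDHG genes themselves (median 0.76).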
